A study of Mus musculus with 8 samples.

How the data were processed

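The deposited values were log2 expression values of Illumina bead arrays, 1 row per gene symbol for 8 arrays; the log base is not given in the sources used here and was taken as 2 from the range of 6.22 to 15.49. Biotinylated cRNA was made from total RNA of sorted GFP-positive cells with the Ambion TotalPrep kit, per the labels' protocols. GenomeStudio, lumi and limma were used by the authors, per the submitters' processing notes, which give no versions, roles or parameters. The sorted columns of the 8 arrays agreed to within 0.0043, as after quantile normalization, and the array medians were 6.90. How several probes of a gene were joined into 1 row is not given in the sources used here. The values came without detection p-values, and the design text of the series speaks of tissues where the labels name sorted GFP-positive cells.

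Row names were upper-case symbols. Of 18131 rows, 14305 matched a current mouse symbol, 2660 an older symbol, 245 an older symbol of a gene that has another row, and 921 matched none and kept the file's name. Names came from the GRCm38.p6 annotation, used only for names. Array depth was not a count. As a background reference, chosen after the data were seen, 1075 olfactory receptor rows had a median of 6.59 and a 95th percentile of 6.81. Where the mean of the dim group was under 6.81, the ratio is given as at least N-fold, computed as the bright group's mean minus the mean, over the arrays of the dim group, of the higher of 6.81 and the gene's own value. No ratio is given where both groups were under it. A mean just above 6.81 is also close to background, so ratios against such means are uncertain. Some genes may read low because of their probe, so a low value does not show that a transcript was absent.

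Groups were taken from the sample titles and tissue labels. Using limma 3.58.1 in R 4.3.3, 1 linear model with a mean per group was fitted to all 8 arrays, without covariates, with empirical Bayes moderation. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 18131 rows, without a fold limit. Gene lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over 37 lists with at least 3 measured genes. The counts of list members are of genes called over all rows, and were repeated with adjustment over the list alone. The 37 lists and the comparisons were fixed before the data were examined. Median, mean and direction of test differed in sign for 9 of 111 list results, none of them called.

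Named genes were the 8 highest and 8 lowest log2 differences per comparison among called genes whose arrays did not overlap, up to 3 called members of each list with the largest difference, and always Neurog3, Pdx1, Mafa and Cdx2. The text takes examples from these. Other genes named in the text were chosen after their values were seen. They were Scg2 and the hormones Ghrl, Pyy, Sct, Gip, Gcg and Insl5 where stated. In the closing observations they were Fgf15, Slc10a2, Defa5, Chga, Chgb, Pcsk1n and Ptprn2.

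The fit was tested on simulated data with the real gene means and the moderated spreads of the fit, in which 200 of 18131 genes were changed. At 1.25-fold, 96% were recovered for gastric against duodenal, 92% for gastric against colonic and 90% for duodenal against colonic cells, and at 1.5-fold and above all were recovered. Among all calls, 5.3%, 8.4% and 5.8% were of unchanged genes. This self-test was written after the first fit to the deposited data. Its noise was normal and independent between genes, and far fewer genes were changed than were called in the data. It therefore shows how the fit behaves under its own assumptions, not its recovery or false calls on the real arrays. Alternatives were quantile normalization again, median centring, a filter on dim genes, trend and robust variance, only the compared groups in the fit, array weights, a replicate block, each array left out, at least 2-fold, an estimated correlation for the lists and, added after the data were seen, only rows matched to a current gene. Listed genes without a row were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.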

Results

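Genome-wide expression was measured with Illumina bead arrays in GFP-positive cells sorted by flow cytometry from adult Ngn3-GFP mice, in which the promoter of Neurog3, the transcription factor that starts endocrine differentiation in the gut, drives GFP. The cells came from the antral (pyloric) stomach (3 arrays), the duodenum (3 arrays) and the colon (2 arrays), and are called gastric, duodenal and colonic here. The table held 18131 gene rows for the 8 arrays. Arrays of the same segment correlated at r = 0.9974 to 0.9980 across genes. Gastric and duodenal arrays correlated at 0.9131 to 0.9142, gastric and colonic arrays at 0.9011 to 0.9023, and duodenal and colonic arrays at 0.9528 to 0.9537. Genes are not independent replicates, so these coefficients only describe similarity. The labels do not say that the arrays came from separate animals, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision, most of all for the colon. The segments were also dissociated differently, the stomach with 2 h of EDTA and Accutase, the duodenum and colon with 30 min of EDTA and dispase.

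The title of the series concerns stomach tissue engineered as a source of beta-cells. The 3 comparisons ask how the GFP-positive cells sorted from the stomach and from the intestine differ. Markers of other cells also differed between the groups, as given below, so cell composition was not held constant. In gastric against duodenal cells, genes of the endocrine lineage and of hormone granules were higher in gastric cells, and intestinal identity, lipid absorption and brush border genes were higher in duodenal cells. The Neurog3 transcript itself stood at 13.03 ± 0.07 (SD, n = 3) on the log2 scale in gastric arrays and at 9.74 ± 0.03 (SD, n = 3) in duodenal arrays, a 9.8-fold difference (log2 difference 3.29, SE 0.05, adjusted p = 2.34e-16). Cdx2, a master regulator of intestinal fate, was 6.01-fold lower in gastric cells (adjusted p = 3.49e-15). Pdx1, a factor of antrum, duodenum and pancreas, was close in both, at 8.95 ± 0.11 (SD, n = 3) and 9.17 ± 0.03 (SD, n = 3) (adjusted p = 0.0172), and without gastric replicate 3 its adjusted p was 0.0936 (0.00422 to 0.0936 over 17 alternatives). Mafa, a beta-cell factor, was at background in both groups (means 6.68 and 6.67). By limma, 8446 of 18131 genes (46.6%) differed, 4115 higher and 4331 lower in gastric cells, and 1408 of them differed at least 2-fold.

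Gut hormone transcripts went both ways between stomach and duodenum. Gast, which encodes gastrin, was 23.1-fold higher in gastric cells (adjusted p = 2.63e-18). All 3 gastric arrays read 15.49 for Gast, the highest value on the scale, so this difference may be compressed. Ratios of other genes near that value may be compressed too. Examples are gastric Sst (15.37 to 15.43), Ghrl (15.25 to 15.27) and Pgc (15.30 to 15.34), and duodenal Sct (15.27 to 15.30). Cck, the cholecystokinin gene, was 15.1-fold lower (10.34 ± 0.05 (SD, n = 3) against 14.26 ± 0.07 (SD, n = 3), adjusted p = 3.71e-17). Nts, the neurotensin gene, was at least 11.6-fold lower, because its gastric mean lay at background. Of the hormone genes that the naming rule did not pick here, Ghrl and Pyy were 3.03-fold and 4.96-fold higher in gastric cells, and Sct, Gip and Gcg were 4.79-fold, 4.18-fold and 7-fold lower. Over the 24 measured genes of the list, 5 were higher, 9 were lower and 10 did not pass the test, and the list as a whole was not called (camera adjusted p = 0.402).

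**Figure D1:**
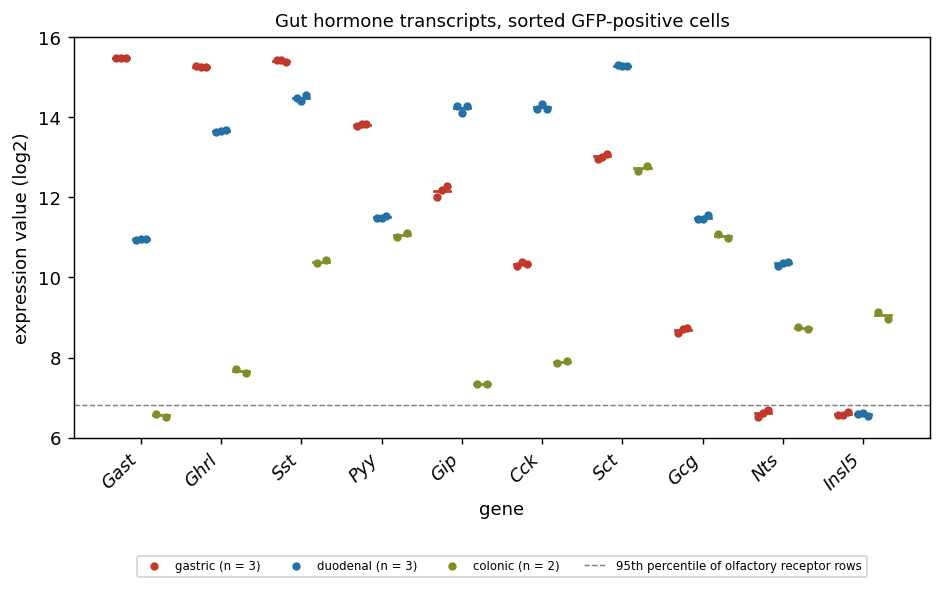
Log2 expression values (vertical axis) of 10 gut hormone genes (horizontal axis) in 3 gastric, 3 duodenal and 2 colonic arrays, with a point per array, a bar at the group mean and a dashed line at the 95th percentile of olfactory receptor rows (6.81). Gast stood at 15.49 in gastric arrays, Cck at 14.26 in duodenal arrays and Insl5 at 9.06 in colonic arrays, and the spread within a group was small against these differences.

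Of 17 genes for granule proteins and prohormone processing, 16 were higher in gastric cells and 1 was lower, with a median log2 difference of 1.94 (camera adjusted p = 1.97e-11). Pcsk2, a prohormone convertase, was 30.8-fold higher, Resp18 9.12-fold and the granin Scg3 8.45-fold. The member that was lower in gastric cells, named after its value was seen, was the granin gene Scg2 (2.67-fold). Among enteroendocrine lineage transcription factors, 21 of 24 were higher (median log2 difference 1.505, adjusted p = 7.87e-12), including Isl1 (8.35-fold) and Hhex (6.41-fold), both developmental regulators. Exocytosis and excitability genes were higher for 17 of 26 (median 0.70, adjusted p = 7.27e-07), among them the calcium channel gene Cacna1h (7.77-fold), the sulfonylurea receptor gene Abcc8 (5.78-fold) and Stx1a (5.47-fold). Beta-cell transcription factors were higher for 13 of 20 and lower for 4 (median 0.40, adjusted p = 5.82e-05). Nkx6-1, which is needed for beta-cell development, was at least 4.69-fold higher in gastric cells, and Insm1 was 5.6-fold higher. Beta-cell function genes were not called as a list (adjusted p = 0.0609), and without gastric replicate 3 the adjusted p was 0.0459 (0.0459 to 0.131 over 17 alternatives). Within this list 13 of 28 genes were higher and 8 lower in gastric cells, with Scgn, a calcium sensor gene, 8-fold higher. In the serotonin and histamine list, 8 of 13 genes were higher and 4 lower (adjusted p = 0.0277, and adjusted p = 0.0836 with an estimated correlation). Hdc, which makes histamine, was 28.7-fold and Slc18a2, a vesicular monoamine transporter gene, 9.99-fold higher, and the serotonin transporter gene Slc6a4 was 4.82-fold lower. Notch and secretory progenitor genes (adjusted p = 0.177) and nutrient and ligand receptors (adjusted p = 0.354) were not called, although the gastrin receptor gene Cckbr was at least 8.15-fold and Mfng, a Notch modifier gene, 5.34-fold higher.

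**Figure D2:**
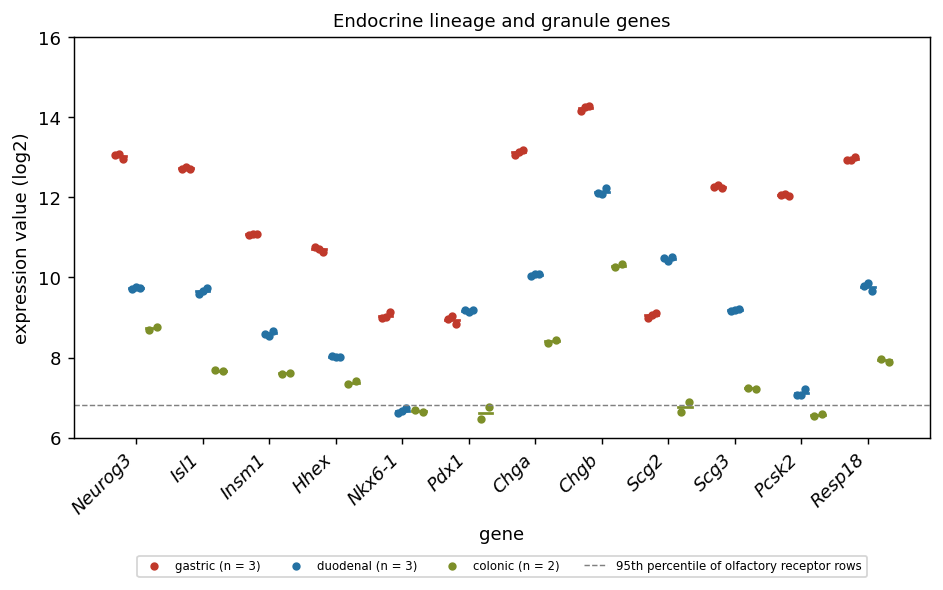
Log2 expression values (vertical axis) of 12 endocrine lineage and granule genes (horizontal axis), with a point per array, a bar at the group mean and a dashed line at 6.81, the 95th percentile of olfactory receptor rows. Pcsk2 stood at 12.06 in gastric arrays and 7.12 in duodenal arrays, while Scg2 stood at 9.05 and 10.47.

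Markers of other epithelial cells moved with these groups. Gastric surface and neck mucous cell genes were higher in gastric cells for all 12 measured genes (median 4.44, adjusted p = 1.34e-15), and chief and parietal cell genes for 9 of 12 (median 3.46, adjusted p = 1.05e-07). The intrinsic factor row GIF was 116-fold, Gkn3 55.1-fold, the pepsinogen gene Pgc 45.2-fold and the proton pump gene Atp4b at least 68.1-fold higher. GIF stood at 14.27 and Atp4b at 12.91 in gastric arrays. Whether these arrays also hold cells of stomach regions other than the antrum was not tested. Gastric epithelial identity genes were higher for 14 of 18 (median 3.15, adjusted p = 4.67e-10), led by the tight junction gene Cldn18 (58.8-fold) and the water channel gene Aqp5 (35.9-fold). Enterocyte genes were lower for 11 of 13 (median -3.04, adjusted p = 3.48e-10), lipid absorption genes for 15 of 19 (adjusted p = 2.02e-10), brush border genes for 15 of 17 (adjusted p = 6.62e-10), xenobiotic metabolism genes for 19 of 22 (adjusted p = 9.43e-12) and intestinal identity genes for 19 of 23 (adjusted p = 4.58e-12). The apolipoprotein gene Apoa4 was 50.3-fold lower in gastric cells, the disaccharidase gene Sis 41.3-fold, the P450 gene Cyp4f14 26.5-fold and the homeobox gene Isx 11.6-fold. Paneth cell genes were lower for 9 of 12, against 3 higher (adjusted p = 8.88e-05), with the defensin gene Defa26 11.8-fold lower, goblet cell genes for 10 of 13 (adjusted p = 5.82e-05), colonocyte genes for 10 of 14 (adjusted p = 5.82e-05), antimicrobial genes for 11 of 19 (adjusted p = 0.000136), and tuft cell genes for 11 of 17, against 3 higher (adjusted p = 0.0251, and adjusted p = 0.0773 with an estimated correlation). Leukocyte genes were lower for 11 of 20 (adjusted p = 0.00254), with the T-cell receptor component gene Cd3g at least 4.09-fold lower. Crypt and gland stem cell genes (adjusted p = 0.823), stromal, endothelial and neural genes (0.387) and red blood cell genes (0.292) were not called. Outside the lists, the row LOC100046120 was 138-fold and Spp1 105-fold higher, and Ido1, a tryptophan-degrading enzyme gene, was 131-fold and Spink1, a trypsin inhibitor gene, 60.1-fold lower in gastric cells.

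Interferon response genes were lower in gastric than duodenal cells for 19 of 21, with a median log2 difference of -1.11 (adjusted p = 1.13e-11). Ifi27l2b was 12.5-fold and Oasl2 7.95-fold lower. Oxidative phosphorylation genes were lower for 20 of 29, or 21 adjusted over the list alone (median -0.28, adjusted p = 1.97e-05), and cell cycle genes for 16 of 23, or 17 adjusted over the list alone (median -0.39, adjusted p = 3e-05). Immediate early genes, which respond to handling of cells, were higher for 11 of 20 and lower for 4 (median 0.56, adjusted p = 0.000793), with Fosb 5.84-fold and Egr1 5.83-fold higher. Glycolysis (adjusted p = 0.911), the unfolded protein response (0.554), ribosomal proteins (0.0536, and 0.0459 without gastric replicate 3, in a range of 0.0459 to 0.109 over 17 alternatives) and Hox genes (0.403) were not called. In all, 24 of 37 lists were called, 9 higher and 15 lower in gastric cells, and 21 held with an estimated correlation. Adjusted over the list alone, the counts of members were the same for 31 lists.

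**Figure D3:**
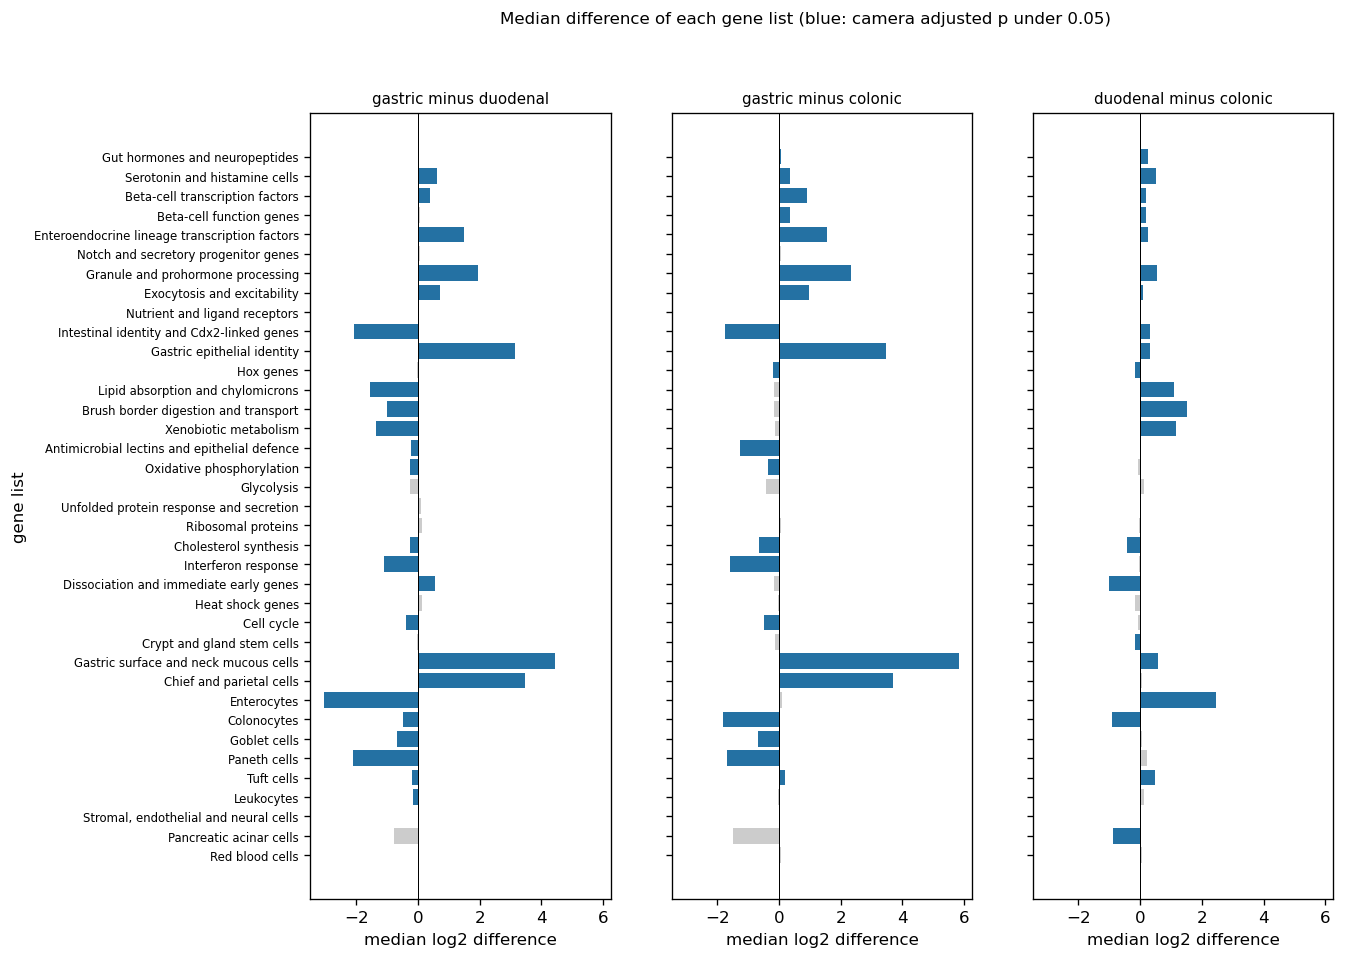
Median log2 difference (horizontal axis, same scale in each panel) of the members of 37 gene lists (vertical axis) in the 3 comparisons, with blue bars for lists with a camera adjusted p under 0.05 and grey bars for the others. The longest bars are those of the gastric surface and neck mucous cell genes, at 4.44 against duodenal and 5.82 against colonic cells.

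Against colonic cells, gastric cells had higher levels of granule and endocrine lineage genes and lower levels of Hox and colonocyte genes. Gast was at least 409-fold higher in gastric cells (adjusted p = 1.78e-20), Ghrl, the ghrelin gene, 192-fold higher (15.26 ± 0.01 (SD, n = 3) against 7.67 ± 0.07 (SD, n = 2)) and Sst, the somatostatin gene, 32.2-fold higher. Of the 24 genes of the hormone list, 10 were higher and 4 lower (median 0.05, adjusted p = 0.0144, and adjusted p = 0.0572 with an estimated correlation). Neurog3 was 19.8-fold higher (log2 difference 4.30, SE 0.06, adjusted p = 3.81e-17), Pdx1 at least 4.39-fold higher and Cdx2 13.9-fold lower, while Mafa was at background in both. By limma, 7993 genes (44.1%) differed, 3668 higher and 4325 lower, and 1344 differed at least 2-fold. All 17 granule genes were higher (median 2.33, adjusted p = 3.09e-17), with Scg3 32.8-fold and Resp18 32.6-fold higher. Lineage transcription factors were higher for 21 of 24, or 22 adjusted over the list alone (adjusted p = 1.28e-15), with Isl1 33.1-fold higher. Exocytosis genes were higher for 18 of 26 (adjusted p = 8.12e-11), beta-cell transcription factors for 13 of 20, against 3 lower (adjusted p = 5.9e-07), with Myt1 9.42-fold higher, and beta-cell function genes for 16 of 28, against 3 lower (adjusted p = 2.35e-05), with Scgn 21.6-fold higher. Serotonin and histamine genes were higher for 9 of 13 (adjusted p = 5.71e-05), with Hdc 49.8-fold and Tph1, which makes serotonin, 9.42-fold higher.

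Hox genes, homeobox genes ordered along the body axis, were lower in gastric than colonic cells for 19 of 36 and higher for none (adjusted p = 1.75e-05). Hoxb7 was at least 6.33-fold and Hoxa7 at least 5.53-fold lower. Gastric mucous cell genes were higher for 11 of 12 (median 5.82, adjusted p = 1.14e-14), chief and parietal genes for 9 of 12 (adjusted p = 1.21e-08) and gastric identity genes for 15 of 18 (adjusted p = 4.31e-15). Pgc was at least 361-fold and Gkn2 at least 333-fold higher. Tuft cell genes were higher for 9 of 17 (adjusted p = 0.000289), among them Avil (10.3-fold). Colonocyte genes were lower for 13 of 14 (median -1.82, adjusted p = 5.72e-11), with Sycn 19.7-fold and Cyp2c55 at least 19.4-fold lower, and intestinal identity genes for 21 of 23 (adjusted p = 1.39e-12), with Cdx1 14.4-fold lower. Paneth cell genes were lower for 10 of 12 (adjusted p = 5.32e-06) and goblet cell genes for 10 of 13, or 11 adjusted over the list alone (adjusted p = 6.05e-06). Antimicrobial genes were lower for 13 of 19 (adjusted p = 3.81e-07), led by the goblet cell gene Retnlb (50.2-fold). The defensin gene Defa31 was at least 110-fold lower, Fabp6, an ileal bile acid binding protein gene, at least 55.4-fold lower and Mptx1 108-fold lower in gastric cells.

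Interferon genes were lower in gastric than colonic cells for 19 of 21 (median -1.60, adjusted p = 9.39e-12), with Ifi47 9.01-fold lower. Oxidative phosphorylation genes were lower for 23 of 29, or 25 adjusted over the list alone (adjusted p = 1.47e-06), and cell cycle genes for 18 of 23 (adjusted p = 7.82e-06). Immediate early genes were not called (median -0.16, adjusted p = 0.275), with Klf4 3.03-fold lower and Egr2 2.5-fold higher. Enterocyte (adjusted p = 0.576), lipid absorption (0.27), brush border (0.214), xenobiotic (0.124) and leukocyte genes (0.348) were not called, although the antigen presentation gene Cd74 was 20.1-fold lower. In all, 21 of 37 lists were called, 11 higher and 10 lower, and 20 held with an estimated correlation. Adjusted over the list alone, the counts of members were the same for 24 lists.

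Duodenal cells had higher levels of hormone, lipid absorption and brush border genes than colonic cells. Gip was 118-fold higher in duodenal cells (14.22 ± 0.10 (SD, n = 3) against 7.34 ± 0.01 (SD, n = 2), adjusted p = 1.74e-17), Cck 82.5-fold and Ghrl 63.4-fold higher, and the hormone list rose with 12 higher and 3 lower (adjusted p = 9.9e-06). Insl5, a hormone gene of the distal gut that the naming rule did not pick, was at background in gastric and duodenal arrays and stood at 9.06 ± 0.12 (SD, n = 2) in colonic arrays. Neurog3 was 2.02-fold higher in duodenal cells (adjusted p = 1.47e-09), Pdx1 at least 5.13-fold higher and Cdx2 2.31-fold lower. By limma, 6203 genes (34.2%) differed, 2909 higher and 3294 lower, and 645 differed at least 2-fold. Granule genes were higher for 14 of 17 (adjusted p = 7.23e-11), with Scg2 at least 12.3-fold and Scg5 5.04-fold higher. Lineage transcription factors were higher for 14 of 24 (adjusted p = 6.9e-06), such as Neurod1 (3.45-fold), beta-cell factors for 10 of 20, against 3 lower (adjusted p = 0.000243), beta-cell function genes for 15 of 28, or 16 adjusted over the list alone (adjusted p = 6.5e-06), exocytosis genes for 10 of 26 (adjusted p = 0.00163) and serotonin and histamine genes for 10 of 13 (adjusted p = 4.07e-06), with Tph1 6.21-fold higher. Enterocyte genes were higher for 11 of 13 (median 2.47, adjusted p = 4.29e-16), lipid absorption genes for 15 of 19 (adjusted p = 1.23e-14), brush border genes for 13 of 17 (adjusted p = 5.01e-11) and xenobiotic genes for 18 of 22 (adjusted p = 1.51e-13). Apoa4 was at least 59.2-fold, Apoa1 51.9-fold and Treh 24.3-fold higher.

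Other-cell markers moved here too. Tuft cell genes were higher in duodenal cells for 12 of 17 (adjusted p = 4.11e-09), with Alox5ap 8.99-fold higher, and gastric mucous cell genes for 9 of 12, against 2 lower (adjusted p = 2.2e-05), with Tff2 14.9-fold higher. Gkn2 stood at 10.76 and Gkn1 at 9.96 in duodenal arrays, while Muc6 (6.58) was at background there. Carry-over of gastric cells or RNA into the duodenal libraries was not tested. Gastric identity genes were higher for 11 of 18 (adjusted p = 4.65e-08). Colonocyte genes were lower for 10 of 14 (adjusted p = 2.71e-07), with Sycn 8.17-fold lower, and Hox genes for 17 of 36 (adjusted p = 4.62e-06), with Hoxb7 at least 6.33-fold lower. Immediate early genes were lower for 17 of 20 (median -1.01, adjusted p = 8.11e-13), with Atf3 4.54-fold lower. Of 23 intestinal identity genes, 13 were higher and 7 lower (adjusted p of the list = 0.0359, and adjusted p = 0.122 with an estimated correlation). Cdx1 (2.09-fold) and Cdx2 were among the lower ones. Crypt stem cell genes were lower for 8 of 15 and higher for 2 (adjusted p = 0.0155, and adjusted p = 0.069 with an estimated correlation). Paneth (adjusted p = 0.113), goblet (0.652), antimicrobial (0.476), interferon (0.552) and leukocyte genes (0.0974, and 0.0417 without colonic replicate 2, in a range of 0.0417 to 0.199 over 17 alternatives) were not called. Some genes of the distal gut and of Paneth cells were nevertheless among the lowest in duodenal cells, such as Defa31 (at least 108-fold), DEFCR-RS10 (at least 51.5-fold), Retnlb (59-fold) and Fabp6 (51.3-fold). In all, 21 of 37 lists were called, 15 higher and 6 lower, and 19 held with an estimated correlation. Adjusted over the list alone, the counts of members were the same for 31 lists.

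**Figure D4:**
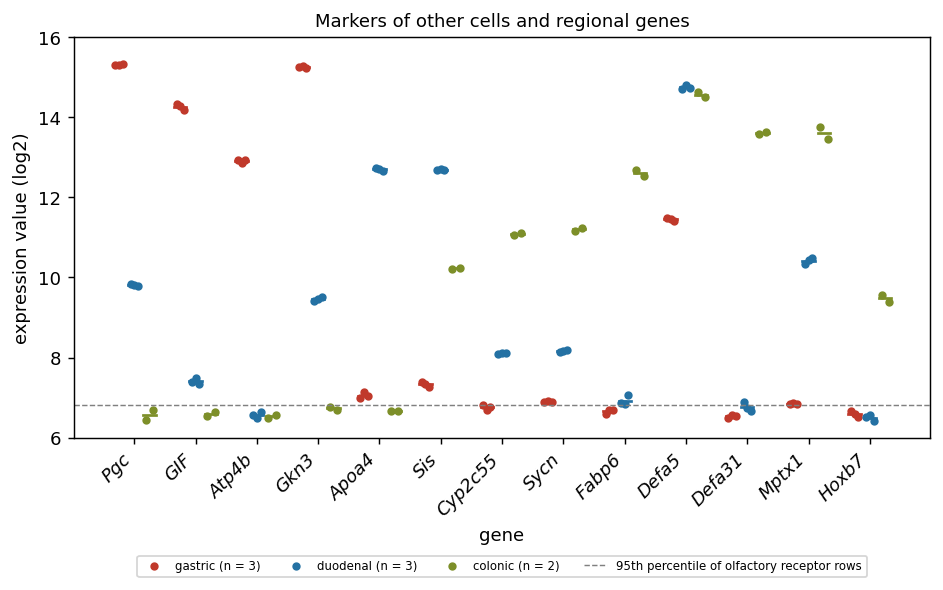
Log2 expression values (vertical axis) of 13 markers of other cells and regional genes (horizontal axis), with a point per array, a bar at the group mean and a dashed line at 6.81, the 95th percentile of olfactory receptor rows. Pgc stood at 15.31 in gastric arrays, Apoa4 at 12.70 in duodenal arrays and Fabp6 at 12.61 in colonic arrays.

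Genes that set the stomach apart from both intestinal segments were counted in both directions. In gastric cells 2888 genes were higher than in duodenal and in colonic cells, and 2889 were lower than in both, and 543 and 338 of these differed at least 2-fold from both. Independent lists of the same sizes would share 832 and 1033 genes. In 100 simulations of unchanged groups 0 genes were shared in either direction, but genes without real differences are rarely called at this threshold, so this value does not bear on the overlap of real differences. The gastric arrays were not divided between the comparisons, and part of the excess may come from sharing them.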

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

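The restriction to rows matched to a current gene was chosen after seeing the data; the other alternatives were planned. With at least 2-fold required, the counts of genes fell to 1408 (gastric against duodenal), 1344 (gastric against colonic) and 645 (duodenal against colonic), and those higher or lower in gastric than in both to 543 and 338, from 8446, 7993, 6203, 2888 and 2889, because the criterion itself keeps fewer genes. Every other alternative run kept these counts within 1.5 times. Leaving out each array gave 7916 to 8433, 7135 to 8160 and 5078 to 6136 genes, 2668 to 2845 higher and 2646 to 2847 lower in gastric than in both, and 24 to 26, 21 to 21 and 21 to 22 lists. A colonic group left with 1 array was assumed to vary like the others. Same-numbered arrays did not deviate together (correlations of deviations from -0.014 to 0.013), so the numbers were not taken to pair them. With the number as a replicate block, 8418, 7830 and 5941 genes were called, 2829 and 2833 in gastric against both, and 24, 21 and 21 lists. The alternative that averages probes was not run, because the table held 1 row per gene. With an estimated correlation 6 list calls were lost, including cholesterol synthesis in gastric against duodenal cells (adjusted p = 0.0736), and the other 5 are given with their lists. With dim genes left out, 5 list calls were lost and the nutrient receptor list was called higher in gastric than colonic cells (adjusted p = 0.0418). No named gene or list that was called in the main fit or in an alternative reversed its direction between them. Changes of sign among results called in neither were not counted. Signal over background limits the lists of lowly expressed genes, such as the nutrient receptors, of which 4 of 24 were above 6.81 in colonic cells.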

Other observations

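The tests below of the Paneth, granule and immediate early gene patterns were chosen, and the reading of the split counts was set down, after those results had been seen, whereas the gene lists were planned. Genes of pancreatic digestive enzymes were present in all segments, with 14 of 16 above 6.81 in gastric cells and 16 in duodenal and colonic cells. Against duodenal cells the list of 16 was higher in gastric cells for 5 genes and lower for 10, and against colonic cells for 5 and 11, and it was not called in either (adjusted p = 0.314 and 0.0675). Its median (-0.77 and -1.48) and its mean (0.77 and 0.21) had opposite signs. Pla2g1b, a pancreatic phospholipase gene, was 76.6-fold and Pnliprp1, a lipase-related gene, 44.8-fold higher in gastric than duodenal cells. In duodenal against colonic cells the list was lower for 14 of 16 genes (adjusted p = 4.23e-08), with Clps, the colipase gene, 8.12-fold higher. Mup1, a major urinary protein gene, was at least 73.4-fold higher in gastric than duodenal cells.

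Cholesterol synthesis genes were lower in gastric than colonic cells for 12 of 15 genes, or 13 adjusted over the list alone (median -0.65, adjusted p = 3.31e-05), and lower in duodenal than colonic cells for 10 (adjusted p = 0.000312). Against duodenal cells they were lower in gastric cells for 11 and higher for 3 (adjusted p = 0.0202, and adjusted p = 0.0736 with an estimated correlation). Heat shock genes were not called in any comparison (adjusted p = 0.554, 0.584 and 0.196), although Hspa1a was 17.1-fold lower in gastric than colonic cells.

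Paneth cell genes, which mark a cell type of the small intestine, were also high in colonic arrays. Defa5 stood at 14.56 ± 0.09 (SD, n = 2) in colonic and at 14.75 ± 0.04 (SD, n = 3) in duodenal arrays. After background subtraction the median colonic signal of 11 Paneth genes was 87.8% of the duodenal signal. Single genes ran from 35.0% (Ang4) to 975% (Mptx1). In gastric cells 12 of 12 measured Paneth genes were above 6.81. Defa5 read 11.42 to 11.48 in gastric arrays, and Mptx1 read 6.84 to 6.87, close to background. A source common to all segments was not tested. The tables argue against duodenal cells or RNA carried into the colonic libraries, because 11 enterocyte genes had a median of 4.3% of their duodenal signal (0.07% to 36.5%), and Defa31, Fabp6 and DEFCR-RS10 were near background in duodenal arrays. Ileal cells in the libraries labelled colonic remain a candidate source: 2 of 3 ileal bile acid genes were above background and higher than in duodenal arrays, but this rests on Fabp6, seen beforehand at 12.61, and on Fgf15 at 7.004 against 6.80, close to background, while Slc10a2 read 6.61 and Fabp6 is also in the brush border list. Colonic genes such as Cyp2c55 (11.09) were also present, and Paneth-like cells of the colon were not tested. A sort for GFP is meant to remove cells without it. Markers of other cells were nevertheless high after the sort, such as Pgc in gastric (15.31) and Apoa4 in duodenal arrays (12.70). The sort therefore cannot be taken to exclude ileal cells of other types.

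Granule genes were higher in gastric than duodenal cells, and a smaller share of endocrine cells in the duodenal sort could lower them all alike. The duodenal signal ran from 9.9% to 27.3% of the gastric signal between the 25th and 75th percentile of 17 genes, a ratio of 2.76, and Scg2 was higher in duodenal cells (2.67-fold). Chga (11.07%), Scg3 (10.08%), Pcsk1n (11.35%) and Resp18 (9.88%) lay close together, while Chgb (23.13%) and Pcsk2 (1.02%) lay apart from them. Ptprn2 (0.0%) had a gastric mean of 6.89, close to background, so its share is uncertain. Whether other cells also express some members was not tested. Vgf (27.28%), at the 75th percentile, and Pcsk1 (34.31%) had duodenal means of 7.04 and 7.01, close to background. Furin (43.8%) and Pam (57.9%) lay higher, so the ratio of 2.76 alone does not decide against a uniform dilution. The direction of Scg2 and the low share of Pcsk2 argue against it as the whole cause for these genes. The close shares of Chga, Scg3, Pcsk1n and Resp18 go with a dilution. A partial dilution, a different mix of endocrine cell types and the segment itself stay open. Other-cell markers differed between the groups as reported, so cell composition was not held constant.

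Immediate early genes differed between segments, and the longer EDTA step for the stomach could raise them. The list was lower in duodenal than colonic cells, with a median log2 difference of -1.007, although both had the same dissociation steps, and it was not called in gastric against colonic cells. That argues against the EDTA step as the whole cause, and a contribution to the gastric and duodenal difference stays open, as does the segment itself.

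The 6 gastric and duodenal arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By limma, the real split called 8446 genes and the highest of the others called 0 (330 at an unadjusted p under 0.05), and 1 split, the real one, gave as many. For the gene lists the real split called 24 and the highest of the others 17, and 1 split gave as many. Each of the other splits puts 2 arrays of a segment with 1 of the other segment, so part of the segment difference remains in it. The mixing also widens the spread within the groups, which lowers the number of genes called. The 0 therefore does not show how many genes the spread between replicates alone would call. In 20 simulations of unchanged groups camera called 0 lists. Genes were drawn independently there, so this value does not bear on lists called because their genes vary together.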
